A study of Mus musculus with 45 samples.

How the data were processed

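Poly(A) RNA from the medial prefrontal cortex of C57BL/6J mice was sequenced in 2 fractions of the same tissue, a total homogenate and cells captured with beads against ACSA2, an astrocyte surface antigen carried by the protein ATP1B2. Per the labels' protocols, ethanol mice had 72 days of alternate-day access to a 15% (v/v) ethanol solution and were killed 24 h after the last drinking day, and control mice drank water. Per the labels, 5% of each cell suspension was kept as homogenate, and the remainder was dissociated, freed of myelin with 25% Percoll and passed over the ACSA2 beads. Libraries were made with 15 PCR cycles and a directional kit and sequenced as 150 bp paired reads, per the labels. Per the submitters' processing notes, bcl2fastq 2.17, cutadapt 1.8, Bowtie2 2.2.5, Picard 1.141, HTSeq 0.5.3p9 and DESeq2 were used with the mouse build mm10. The deposited values are raw read counts per gene symbol, 24421 genes per library, with 5 tally lines that name no gene. The strand setting of the counting, the gene annotation and the treatment of duplicate reads are not given in the sources used here, so reads of genes that overlap on opposite strands cannot be told apart.

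The labels describe 45 samples from 24 mice. Counts from 44 libraries were used: 10 isolated fractions and 12 homogenates of water mice, and 10 isolated fractions and 12 homogenates of ethanol mice. A further isolated fraction, from water mouse 72, was not analysed here. Groups were taken from the labels. The tally lines were left out of library sizes and tests. Reads not aligned made up 37.4% to 90.3% of the isolated libraries and 18.0% to 55.2% of the homogenates. Reads aligned outside genes made up 4.05% to 20.6% and 18.8% to 36.2%, and ambiguous reads at most 0.270% and 0.381%. In a permutation test of each tally, the difference between ethanol and water libraries had p values from 0.102 to 0.732. The ribosomal RNA gene Rn45s took 0.282% to 5.98% of the gene counts in water isolated libraries and stayed in the fits.

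Total gene counts ranged from 504492 to 3248804 in the isolated libraries and from 3673811 to 9109247 in the homogenates. A floor of 3 counts, the upper limit that a count of 0 allows, corresponded to 0.923 to 5.95 CPM (read counts scaled by library size) in single isolated libraries and to 0.329 to 0.817 CPM in single homogenates. For genes at 0 in every isolated library of the water mice, the floor was taken over the group, at 0.206 CPM. Floors cover counting error only, since reads amplified by PCR are not independent molecules. Intervals of fold changes also include the spread between mice. No 2 libraries of a group were copies of each other, with Pearson correlations of log2 CPM from 0.955 to 0.996.

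Differential expression was tested on the deposited counts with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with robust estimation, trimmed mean scaling (TMM) and the expression filter of edgeR by group. P values were adjusted by the Benjamini-Hochberg method, and genes with a false discovery rate (FDR) under 0.05 were called. The effect of ethanol was fitted within each fraction with its own dispersions, because bead isolation can change the spread between animals. The difference of the ethanol effects between the fractions came from 1 model of all 4 groups, and the isolated fraction was compared with the homogenate in water mice alone. The limma 3.58.1 test camera, with its preset correlation of 0.01, compared 13 cell type marker lists and 32 gene lists with all other genes, where at least 5 members were tested. Camera with a correlation estimated from the data and fry, which tests whether the genes of a list move one way without comparing them with other genes, were run beside it. The mean log2 CPM (prior count 2) of each marker list per library was compared between ethanol and water mice with a two-sided permutation test of 100000 resamples. The samples, tests, lists, naming rule and most alternatives were fixed before the data were examined.

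The genes named follow a rule. In each comparison these were the 6 genes with the largest change and the 6 with the lowest p in each direction among called genes with a mean of at least 20 counts per library. Where fewer than 6 passed, the 6 with the lowest unadjusted p in each direction could be named as not past the threshold, with up to 4 members of each list described. Predicted genes were skipped for the largest changes. Genes named outside this rule were chosen after their values were seen, and the text says so. Gene positions are on GRCm38 (mm10) from GENCODE M21 and were matched by symbol.

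Libraries of the 2 fractions share a mouse number, and the homogenate is an aliquot of the suspension from which the isolated cells came, per the labels, so the numbers pair the libraries. Deviations from the group means correlated with a median of 0.0487 (from -0.118 to 0.236) in the 20 pairs with the same number and of -0.00413 between other numbers. In 8 of the 20 pairs the correlation was above 0.1, as in 35 of 220 pairs of other numbers with the same treatment. The correlation was highest with the own number in 5 of the 20. A fit with the mouse as a replicate block called 0 genes higher and 0 lower for the difference of the ethanol effects. For the isolated fraction against the homogenate it called 4737 genes higher and 5102 lower.

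The fits were tested on simulated data with the library sizes, group sizes and dispersions of each comparison. In each simulation 50 genes were changed at each fold, all at once, and genes varied independently. An FDR threshold is harder to pass where few genes change. Real libraries also share variation between genes, so recovery in them may be lower. In the isolated fraction 54% of genes changed 1.5-fold were recovered, 88% of those changed 2-fold, 88% at 3-fold and 94% at 4-fold. In the homogenate the recovered shares were 80%, 86%, 90% and 98%. For the difference between the fractions they were 36%, 82%, 88% and 92%, and for the isolated fraction against the homogenate 50%, 82%, 98% and 94%.

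The alternatives tried were median-of-ratios and upper-quartile scaling, the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, no filter on low counts, a mean of at least 50 counts, an FDR under 0.1, 1 fit of all 4 groups, counts thinned to the smallest library, the replicate block, and leaving out each replicate in turn. The mean levels of the neuron, oligodendrocyte, microglia and endothelial marker lists were also fitted as 4 covariates, and the main axis of the non-astrocyte markers as 1. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for gene positions and figures. The value of 1 astrocyte marker is not reported here.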

Results

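Gene expression was measured by RNA sequencing in the medial prefrontal cortex of mice that drank ethanol or water, in total homogenate and in cells isolated with beads against the astrocyte antigen ACSA2. The isolated fraction was measured in 10 water and 10 ethanol mice, and the homogenate in 12 water and 12 ethanol mice. Of the 24 mice, 20 gave both fractions. Total gene counts per library had a median of 1012301 in isolated fractions of water mice (504492 to 2938854) and 1406652 in those of ethanol mice (1028493 to 3248804). In homogenates the medians were 5886872 (3973666 to 7837038) and 6266918 (3673811 to 9109247). In the isolated fraction 5 water libraries and 0 ethanol libraries held under 1000000 counts. Between 13810 and 16009 genes had counts in each isolated library, and between 16209 and 17533 in each homogenate. All values are normalised read counts (CPM, counts scaled by library size) or log2 fold changes ± SE unless stated otherwise.

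The isolated fraction was first compared with the homogenate in water mice (n = 10 and 12), to describe which cells the isolation retained. Transcripts of neurons were far lower in the isolated fraction, and those of astrocytes, microglia, oligodendrocytes and vessel wall cells were higher. Of the 23 astrocyte markers, 19 were higher and 1 was lower, with a median log2 fold change of 0.99. Examples were the growth factor receptor gene Fgfr3 (1.64 ± 0.10), the zinc transporter gene Slc39a12 (1.69 ± 0.11) and Glul, which encodes glutamine synthetase (1.10 ± 0.09). Gfap, the intermediate filament gene of astrocytes, was the 1 lower marker (-2.13 ± 0.32), and Atp1b2, which encodes the capture antigen, was higher by 0.93 ± 0.12. These 2 genes were chosen after their values were seen. All 20 neuronal markers were lower, with a median of -4.29, among them Tubb3 (-3.59 ± 0.15), Eno2 (-3.78 ± 0.17), Syp (-3.82 ± 0.17) and Rbfox3 (-4.68 ± 0.24).

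By median log2 fold change, transcripts of microglia, oligodendrocytes, mural cells and endothelial cells lay above those of astrocytes. The oligodendrocyte precursor list (median -0.47), the list of vascular and meningeal fibroblasts (0.06) and that of ependyma and choroid plexus (-3.01) did not. Of these differences from astrocytes, only that of microglia was tested, as given further below. All 17 microglial markers were higher, with a median log2 fold change of 3.68, including the purinergic receptor genes P2ry13 (3.78 ± 0.12) and P2ry12 (3.75 ± 0.13) and the chemokine receptor gene Cx3cr1 (3.67 ± 0.12). All 16 oligodendrocyte markers were higher, with a median of 3.18, for example Aspa (3.37 ± 0.20) and Ugt8a (3.19 ± 0.22). All 9 mural cell markers tested were higher, with a median of 2.64, and all 15 endothelial markers, with a median of 1.34. In percent of gene counts, the astrocyte list made up 2.34% ± 0.663 (SD, n = 10) of the isolated fraction and 1.36% ± 0.10 (SD, n = 12) of the homogenate. The microglial list made up 1.16% ± 0.240 and 0.0851% ± 0.0138, the oligodendrocyte list 2.16% ± 0.462 and 0.359% ± 0.242, and the neuron list 0.0754% ± 0.0345 and 1.26% ± 0.106.

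**Figure D1:**
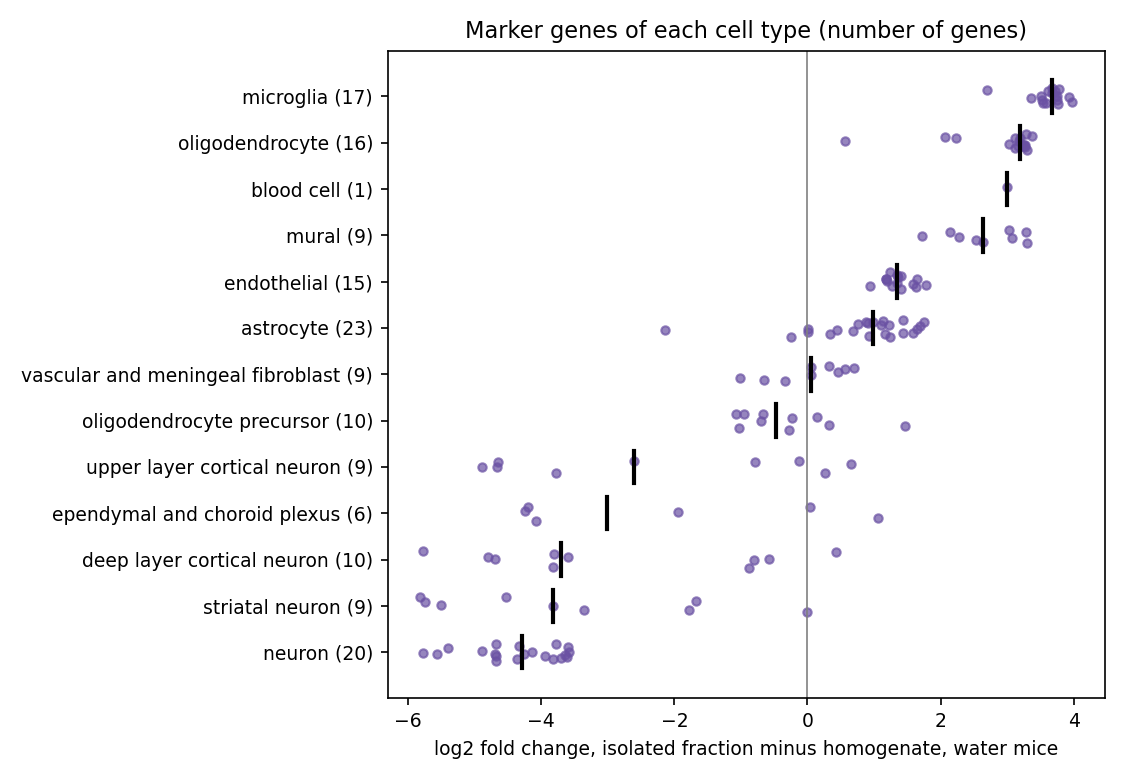
Log2 fold change of each cell type marker gene between the isolated fraction and the homogenate of water mice, with 1 point per gene and a bar at the median of each list. The microglia, oligodendrocyte and mural lists lie at medians of 3.68, 3.18 and 2.64, the astrocyte list at 0.99 and the neuron list at -4.29.

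Genes of inflammation and stress were among the most raised in the isolated fraction. Per the labels, the homogenate was kept from the cell suspension, and only the remainder was then dissociated, freed of myelin and captured on beads. Handling and cell type therefore cannot be told apart in this comparison. The largest changes were those of the cytokine and chemokine genes Tnf (9.10 ± 0.34), Ccl3 (8.42 ± 0.24), Il1b (8.22 ± 0.31), Cxcl2 (8.20 ± 0.44), Ccl4 (8.13 ± 0.28) and Il1a (8.02 ± 0.29). Tnf stood at 177 ± 67.2 CPM (SD, n = 10) in the isolated fraction and at 0.332 ± 0.484 CPM (SD, n = 12) in the homogenate. The higher genes with the lowest p were Ppp1r15a (5.21 ± 0.13), a phosphatase subunit gene of the integrated stress response, Neurl3 (6.38 ± 0.16), Il10ra (5.00 ± 0.13), Socs3 (5.60 ± 0.15), Icam1 (7.12 ± 0.19) and Zfp36 (7.23 ± 0.20). Of the 24 Toll-like receptor and NF-kB genes tested, 23 were higher and 1 was lower (median 2.77). Of the 22 immediate early genes, 16 were higher, 5 were lower and 1 did not pass (median 2.46), with Klf4 at 5.19 ± 0.16, Jun at 5.09 ± 0.16 and Dusp1 at 3.94 ± 0.13. Of the 14 heat shock genes, 12 were higher (median 1.30), led by Hspa1a (5.87 ± 0.18), and all 11 antigen presentation genes were higher (median 2.21), led by H2-K1 (3.93 ± 0.12).

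Genes of neuronal signalling were lower in the isolated fraction. Among glutamate receptor genes 20 of 22 were lower (median -3.78), among calcium handling genes 29 of 34 (median -2.37), and among genes of GABA receptors and uptake 13 of 17 (median -2.84). The lower genes with the lowest p included Fam155a (-4.84 ± 0.14), the mitogen-activated protein kinase scaffold gene Mapk8ip2 (-4.21 ± 0.12), the vesicular transporter gene Slc6a17 (-4.04 ± 0.12) and the chromatin remodeller gene Chd5 (-4.41 ± 0.14). Kcns3, Npy5r and Alox12b had 0 counts in every isolated library of the water mice. Against a floor of 3 counts over the group, Kcns3 was at least 30.3-fold lower, Npy5r at least 26.4-fold and Alox12b at least 28.8-fold. No list held such a gene.

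In this comparison 13434 genes were tested with edgeR, of which 4994 were higher and 5418 lower in the isolated fraction at an FDR under 0.05, and 2557 and 2996 of these by at least 2-fold. Camera called 19 of the 43 lists tested up and 5 down. Fry, which does not compare a list with other genes, called 28 up and 10 down. With an estimated correlation 2 calls of camera held, those of the calcium handling list and the GABA list, each with an adjusted p = 0.0333 with an estimated correlation. For the lists described above that lost their call, the adjusted p ranged from 0.0509 for the microglial list with an estimated correlation to 0.582 for the astrocyte list. Upper-quartile scaling moved the median of all genes by 0.11, so fold changes in this comparison hold relative to that shift. The libraries also differed in depth, and with every library thinned to the smallest total 3322 genes were higher and 3283 lower among 8859 tested.

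The effect of ethanol on the isolated fraction was the main question of the series, and none of the 11122 genes tested passed an FDR of 0.05 in edgeR. Among the fixed lists, that of mural cells, the pericytes and smooth muscle cells of vessel walls, had the highest median log2 fold change in ethanol mice, and the astrocyte markers lay together below the water level. Gprc5c, an orphan G protein-coupled receptor gene, had 26.8 ± 5.52 CPM (SD, n = 10) in water mice and 47.8 ± 11.6 CPM (SD, n = 10) in ethanol mice, a log2 fold change of 0.87 ± 0.16 (edgeR FDR 0.0719), and lay above the water mean in 9 of 10 ethanol libraries. Amotl2, an angiomotin family gene, stood at 144 ± 19.1 and 201 ± 25.9 CPM (0.49 ± 0.09, FDR 0.109), and Cspg4, the NG2 proteoglycan gene carried by pericytes and oligodendrocyte precursors, at 149 ± 27.6 and 212 ± 35.5 CPM (0.51 ± 0.11, FDR 0.135). The Notch target gene Heyl (0.76 ± 0.16), the cation transporter gene Atp13a5 (0.69 ± 0.14) and Dact1 (0.90 ± 0.19), a gene of the Wnt pathway, were the other three with the lowest p among higher genes. On the lower side these were Negr1, which encodes a neuronal adhesion protein (38.3 ± 6.65 and 26.4 ± 6.72 CPM, -0.59 ± 0.13, FDR 0.161), Lxn (-0.60 ± 0.15), the lactate dehydrogenase gene Ldhb (-0.40 ± 0.12), the transcription factor gene Pax6 (-0.52 ± 0.15), Lonrf2 (-0.61 ± 0.19) and the clock gene Bhlhe41 (-0.30 ± 0.09).

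On build mm10 Gprc5c lies on chromosome 11 (114851152 to 114872617), Amotl2 on chromosome 9 (102716672 to 102733418), Cspg4 on chromosome 9 (56865033 to 56899870), Negr1 on chromosome 3 (156561794 to 157316445) and Lxn on chromosome 3 (67457998 to 67463926). Lxn overlaps exons of Gfm1 on the opposite strand, so its counts are uncertain. The same holds, with other genes on the opposite strand, for Dact1, Bhlhe41, Abcc9, Nid1, Col4a1, Idi1, Gabra4, S1pr3, Hspa1a, Tmem88, Fdxacb1, Acot3, Nkiras2, Ercc1, Gpr17, Penk, Slirp and Dleu7. In the comparison of the fractions it holds for Fgfr3, Glul, Syp, P2ry12, Cx3cr1, Il1a, Il1b, Ppp1r15a, Icam1, Zfp36, Dusp1, Jun, Hspa1a and Chd5.

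**Figure D2:**
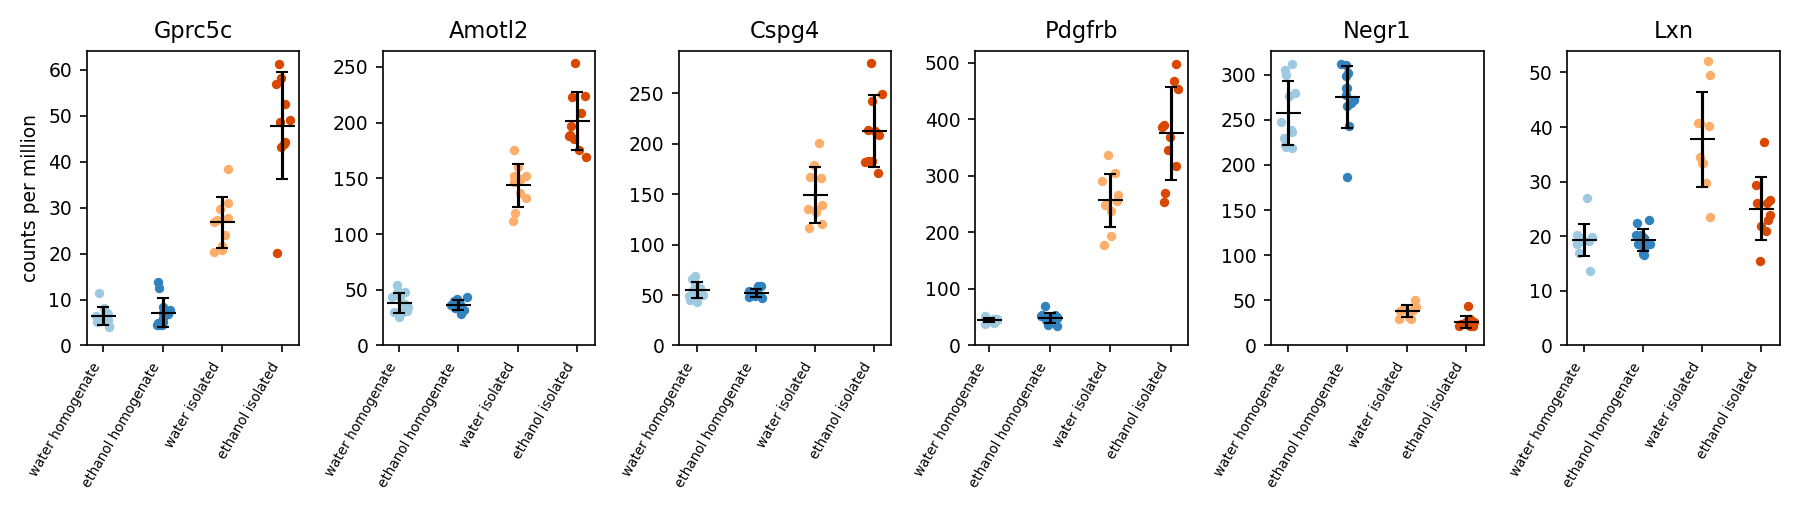
CPM of 6 genes in every library of the 4 groups, with 1 point per library and the mean with its SD. In the isolated fraction Gprc5c stood at 26.8 CPM in water and 47.8 CPM in ethanol mice, and Negr1 at 38.3 and 26.4 CPM.

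The mural marker list was called up by camera in ethanol mice. Its median log2 fold change was 0.49, 8 of its 9 members tested lay above 0, 0 passed over all genes and 6 were higher when adjusted over the list alone (camera FDR 9.0e-10). The call was lost with an estimated correlation (adjusted p = 0.0657 with an estimated correlation). The 4 members with the lowest p were pericyte genes: the receptor gene Pdgfrb (0.55 ± 0.13), the potassium channel genes Abcc9 (0.68 ± 0.16) and Kcnj8 (0.60 ± 0.17), and the vitronectin gene Vtn (0.49 ± 0.13). The mean level of the mural list was 6.30 ± 0.289 log2 CPM (SD, n = 10) in water and 6.69 ± 0.283 (SD, n = 10) in ethanol mice, a difference of 0.386 ± 0.128 that was positive in 9 of 10 ethanol libraries (permutation p = 0.00789, FDR 0.0513 over 13 lists). The endothelial list differed by 0.119 ± 0.173 (permutation p = 0.50). All 15 of its members lay above 0, but camera did not call it (median 0.13, camera FDR 0.0593). In the extracellular matrix list 15 of the 24 members tested lay above 0, 0 passed over all genes and 3 were higher when adjusted over the list alone (median 0.04, camera FDR 0.0256, adjusted p = 0.515 with an estimated correlation). The members with the lowest p included Nid1 (0.63 ± 0.15), Lamc1 (0.40 ± 0.11) and Col4a1 (0.41 ± 0.12).

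Astrocyte markers pointed down together. All 23 had negative log2 fold changes, with a median of -0.24, and 0 passed either over all genes or adjusted over the list alone (camera FDR 7.6e-08, adjusted p = 0.515 with an estimated correlation). The lowest p belonged to the glycogen-targeting gene Ppp1r3c (-0.56 ± 0.18), the gap junction gene Gjb6 (-0.43 ± 0.19), Ntsr2 (-0.31 ± 0.14) and the clusterin gene Clu (-0.30 ± 0.14). The mean level of the list was 8.68 ± 0.369 log2 CPM in water and 8.47 ± 0.262 in ethanol mice (SD, n = 10 each, permutation p = 0.158), a difference of -0.213 ± 0.143. Without the libraries under 1000000 counts, all of them from water mice, it was -0.394 ± 0.176 (permutation p = 0.0233, FDR 0.162), with all 10 ethanol libraries below the water mean. Camera also called 7 other lists down. These were the neuron list (12 tested, median -0.38), microglia (17, -0.19), cholesterol synthesis (24, -0.16), glycolysis and glycogen (24, -0.15), GABA receptors and uptake (11, -0.23), potassium and water channels and gap junctions (15, -0.19) and the nuclear-encoded respiratory chain (67, -0.09). The neuron list was at 0.08 without the libraries under 1000000 counts. In these 7 lists 0 members passed over all genes, and 1 did when adjusted over the list alone, Ldhb of the glycolysis list. In cholesterol synthesis Sqle stood at -0.40 ± 0.14 and Idi1 at -0.43 ± 0.16, and the GABA-A receptor gene Gabra4 stood at -0.54 ± 0.18. None of the 7 calls held with an estimated correlation, where the adjusted p lay between 0.459 for the GABA list and 0.594 for the list of potassium and water channels.

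The lists called up beside the mural and extracellular matrix lists were those of shared reactive astrocyte genes (7 tested, median 0.25), heat shock (14, 0.17) and immediate early genes (20, 0.10). Of the reactive genes, the sphingosine receptor gene S1pr3 was the 1 member higher when adjusted over the list alone (0.53 ± 0.13), whereas Gfap stood at -0.32 ± 0.25. Hspa1a stood at 0.30 ± 0.18 and Nr4a1 at 0.27 ± 0.10. Their adjusted p values with an estimated correlation were 0.0675, 0.515 and 0.594. The list of ethanol and acetaldehyde metabolism was not called (9 tested, median -0.13, camera FDR 0.0784). Interferon response genes (12 tested, median 0.11) and Toll-like receptor and NF-kB genes (24 tested, median 0.05) were not called either. Among markers of other cell types, the upper layer cortical neuron list was lower in ethanol libraries by -0.286 ± 0.0802 log2 CPM (permutation p = 0.00331, FDR 0.0430, 9 of 10 ethanol libraries under the water mean). That difference did not pass without the libraries under 1000000 counts (-0.217 ± 0.0716) or as a median z-score of the members, and camera did not call the list (6 tested, median -0.11).

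**Figure D3:**
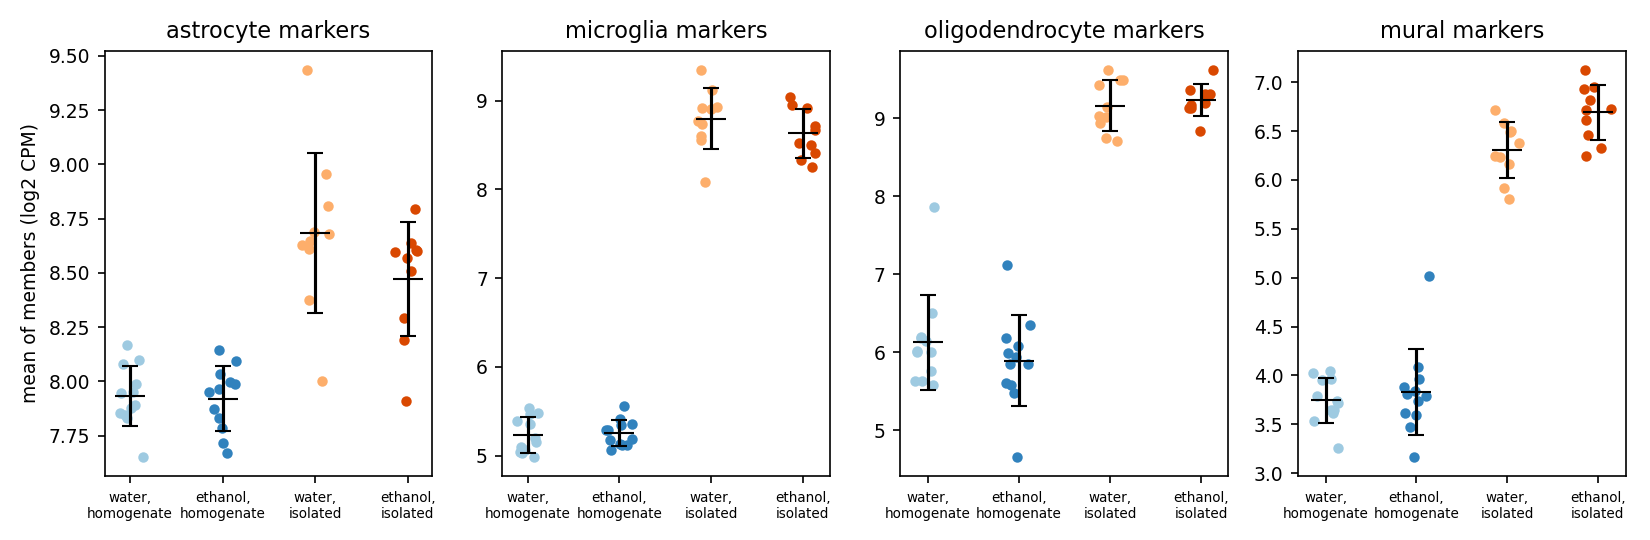
Mean log2 CPM of the astrocyte, microglia, oligodendrocyte and mural marker lists in each library of the 4 groups, with the mean and SD. In the isolated fraction the mural level stood at 6.30 in water and 6.69 in ethanol mice, and the astrocyte level at 8.68 and 8.47.

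At an unadjusted p under 0.05 edgeR gave 600 genes, where 556 would be expected by chance, and the lowest FDR was 0.0719. The DESeq2 Wald test called 12 genes higher and 2 lower, and limma voom 3 higher and 2 lower. Amotl2, Gprc5c, Cspg4 and Negr1 were called by both, and the DESeq2 genes also held the pericyte genes Pdgfrb and Abcc9. Intervals had a median half-width of 0.30 on the log2 scale (1.23-fold), and for 97.9% of the genes they lay inside a 2-fold change, so larger changes were excluded for most genes. In simulated data with the same library sizes, where many genes were changed at once, 54% of 1.5-fold changes were recovered. Fewer would be expected to pass if only few genes changed. Leaving out ethanol library 77, in which Gprc5c was lowest, gave 14 higher genes, leaving out ethanol library 75 gave 10, leaving out water library 82 gave 1, and leaving out ethanol library 66 gave 1 lower gene, Negr1.

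With the mean levels of the neuron, oligodendrocyte, microglia and endothelial lists as 4 covariates, 71 genes were higher and 176 lower in the isolated fraction of ethanol mice. All 247 had the same sign without the covariates. Of the 23 astrocyte markers 17 were among the lower genes in the fit with 4 covariates, for example Ppp1r3c (-0.68 ± 0.10) and Clu (-0.47 ± 0.07), and Cspg4 (0.53 ± 0.09), Gprc5c and Amotl2 were among the higher ones. With the astrocyte list as a further covariate, 0 genes were higher and 0 lower. The median SE of the lower genes outside the list then grew from 0.10 to 0.20 and their median log2 fold change went from -0.43 to -0.15. For the 71 higher genes the median SE grew from 0.11 to 0.23 and the median log2 fold change went from 0.46 to 0.22. With the main axis of the non-astrocyte markers as 1 covariate instead, edgeR called 0 genes higher and 0 lower, with a lowest FDR of 0.135 and 791 genes at an unadjusted p under 0.05.

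**Figure D4:**
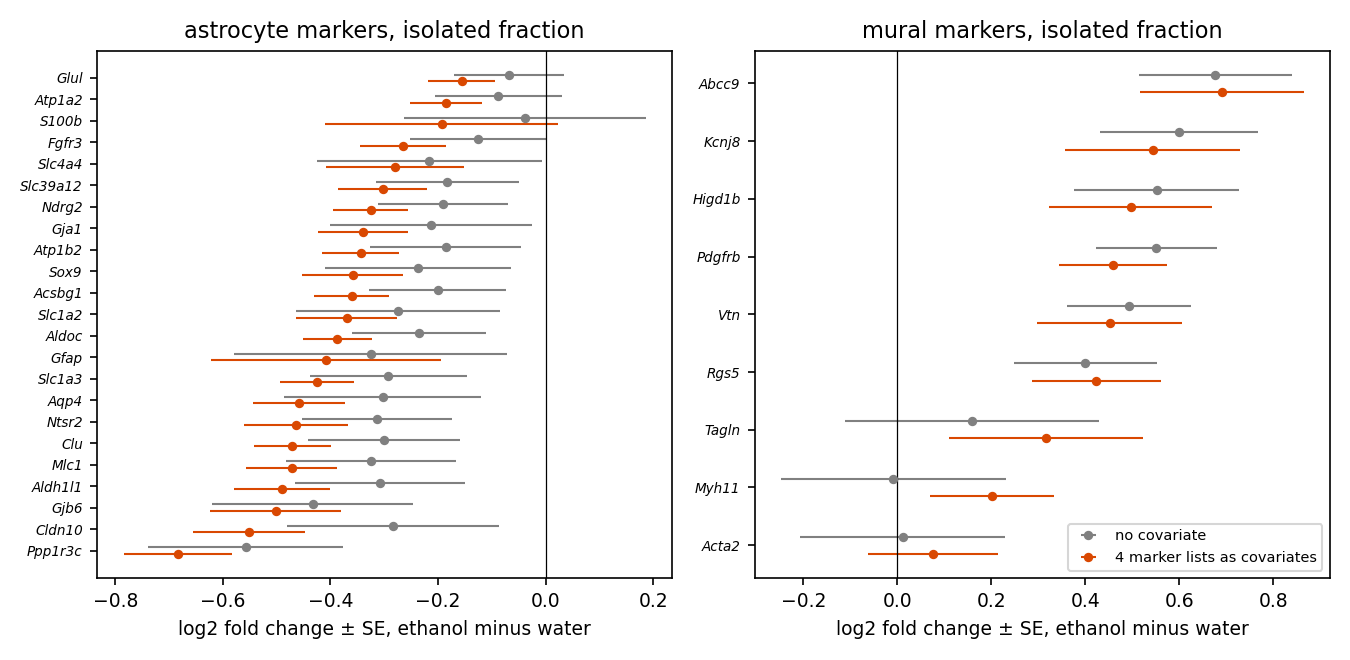
Log2 fold change ± SE between ethanol and water mice for the astrocyte markers (left) and mural markers (right) in the isolated fraction, without covariates (grey) and with 4 marker lists as covariates (orange). With the covariates 17 of the 23 astrocyte markers were lower at an FDR under 0.05 and 1 mural marker was higher.

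In total homogenate, the ethanol effect was tested for 13576 genes in 12 water and 12 ethanol mice, and 0 were higher and 0 lower. The higher gene with the lowest p was Atp2b4, which encodes a calcium pump of the plasma membrane, at 461 ± 86.2 CPM in water and 615 ± 110 CPM in ethanol mice (SD, n = 12 each), a log2 fold change of 0.42 ± 0.11 (edgeR FDR 0.979). It was followed by Tmem88 (0.69 ± 0.18), Fdxacb1 (0.41 ± 0.11) and Acot3 (0.78 ± 0.23). The lower genes with the lowest p were Nkiras2 (-0.31 ± 0.09), the kinase gene Cdk8 (-0.24 ± 0.07) and the DNA repair gene Ercc1 (-0.26 ± 0.08), each with an FDR of 0.979. Atp2b4 was the 1 gene of the calcium handling list higher when adjusted over the list alone.

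Lists of white matter and of neighbouring regions were among the few called in homogenate. Camera called the oligodendrocyte precursor list (10 tested, median -0.17, 0 above 0), the oligodendrocyte list (16, -0.31, 0 above 0), the striatal neuron list (11, -0.48, 0 above 0) and the nuclear-encoded respiratory chain (77, -0.04) down, and the upper layer cortical neuron list (9, 0.22, 8 above 0) and the endothelial list (15, 0.12, 14 above 0) up. No member of these lists passed over all genes or adjusted over the list alone, and no call held with an estimated correlation, where the adjusted p was 0.681 for the oligodendrocyte precursor list and 0.893 for the other five. Examples were the precursor gene Gpr17 (-0.23 ± 0.09), the striatal genes Adora2a (-1.14 ± 0.52) and Penk (-0.80 ± 0.41), and the endothelial gene Vwf (0.48 ± 0.22). Water homogenates 68 and 73 stood apart on the first principal component, and without them the oligodendrocyte (median 0.02), striatal (-0.11) and upper layer (0.10) lists were not called, with Adora2a at -0.43 ± 0.43 and Penk at -0.47 ± 0.41. The oligodendrocyte level then differed by -0.0740 ± 0.194 log2 CPM, against -0.235 ± 0.244 with all libraries, and the striatal level by -0.0480 ± 0.227, against -0.191 ± 0.295. The precursor (-0.18), respiratory chain (-0.04) and endothelial (0.08) lists were still called. The mean level of the precursor list was 4.68 ± 0.226 log2 CPM in water and 4.50 ± 0.108 in ethanol mice (SD, n = 12 each, permutation p = 0.0226, FDR 0.294), and lay below the water mean in all 12 ethanol libraries. The mural list differed by 0.0869 ± 0.144 (permutation p = 0.599) and the astrocyte list by -0.0114 ± 0.0586 (permutation p = 0.846). All 9 mural members tested lay above 0 in homogenate too, but camera did not call that list (median 0.13, camera FDR 0.0763).

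The homogenate gave 467 genes at an unadjusted p under 0.05, fewer than the 679 expected by chance, and the DESeq2 Wald test and limma voom called 0 genes. Intervals had a median half-width of 0.19 on the log2 scale.

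Whether the ethanol effect differed between the fractions was tested for 14087 genes in all 44 libraries, and 0 were higher and 0 lower in the isolated fraction relative to the homogenate. The lowest p belonged to Negr1, with a difference of log2 fold changes of -0.70 ± 0.15, and Cspg4, with 0.57 ± 0.13 (edgeR FDR 0.271 for both). Among higher genes Car12 (4.06 ± 0.98), Dact1 (0.96 ± 0.24), Zfp599, Amotl2 (0.55 ± 0.14) and Stk39 (0.42 ± 0.11) followed. Car12 stood at only 0.328 ± 0.797 CPM (SD, n = 10) in isolated fractions of water mice and 2.31 ± 3.79 CPM (SD, n = 10) in those of ethanol mice, and Zfp599 had 0 counts in the former, so no fold is given for it. Among lower genes Slirp (-0.96 ± 0.24), Dleu7 (-2.90 ± 0.72), Lxn (-0.61 ± 0.16), Herpud2 (-0.32 ± 0.09) and Mblac1 (-1.30 ± 0.35) followed, with Dleu7 at 0.843 ± 0.820 and 0.0560 ± 0.177 CPM (SD, n = 10 each) in isolated fractions of water and ethanol mice. Camera called 6 of the 43 lists up and 7 down. The mural (median 0.39), oligodendrocyte (0.37), ependymal and choroid plexus (0.87) and heat shock (0.16) lists were among those up, and the astrocyte (-0.25), upper layer neuron (-0.41), microglia (-0.18) and GABA (-0.18) lists among those down. Without water homogenates 68 and 73 only 2 lists were up, mural (0.40) and heat shock (0.15), while the oligodendrocyte list (0.04) and the ependymal and choroid plexus list (0.44) were not called. The 4 lists named as down were called down there too. None held with an estimated correlation, where the adjusted p values of these 8 lists lay between 0.50 for the GABA list and 0.752 for the oligodendrocyte list. At an unadjusted p under 0.05 there were 834 genes, where 704 would be expected by chance. The DESeq2 Wald test called 1 gene higher and 1 lower, and limma voom 1 higher and 0 lower. Leaving out the isolated fraction of ethanol mouse 66 or the homogenate of ethanol mouse 76 gave 1 lower gene, Negr1.

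Across the 10938 genes tested in both fractions, the log2 fold changes of ethanol in the isolated fraction and in the homogenate had a Spearman correlation of -0.0645 and a Pearson correlation of -0.0434, and 46.9% had the same sign. Genes are not independent replicates, so treatment was permuted over mice 1000 times, with a correlation of differences in log2 CPM of -0.0963 against a permuted range of -0.132 to 0.237 (permutation p = 0.317). Of the genes with an unadjusted p under 0.05, 4 were higher in both fractions where 4.03 were expected, and 2 were lower in both where 4.66 were expected.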

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

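The comparisons of mural with other markers, the test of microglial transcripts and the test on thinned counts were chosen after the results were seen. So were the tests with 4 marker lists as covariates of fewer cells of another type and of dilution. The fit with the astrocyte list as a further covariate and the fits of marker levels without libraries under 1000000 counts were also chosen then. The other tests were planned. Differences of list medians below come from the test of the difference between fractions, and samples standing apart come from 58 series of 10 or fewer libraries, of which 6 held one. Chance alone marks about 1 in 20 such series.

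In single libraries, the blood cell marker level of the isolated fraction of water mouse 73 was -0.530 log2 CPM, against 0.922 to 2.34 in the others of its group. Bhlhe41 was at 7.29 log2 CPM in the isolated fraction of water mouse 82, against 6.86 to 7.09. Reads not aligned made up 37.4% in the isolated fraction of ethanol mouse 60, against 59.6% to 81.5%. The striatal neuron level was 3.06 log2 CPM in the isolated fraction of ethanol mouse 66, against 1.90 to 2.50, and Negr1 was at 5.47 in the same library, against 4.44 to 4.90. Gprc5c was at 4.36 log2 CPM in the isolated fraction of ethanol mouse 77, against 5.45 to 5.95.

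By camera with its preset correlation, the ethanol effects of 13 lists differed between the fractions, isolated minus homogenate. The medians were 0.39 for mural, 0.37 for oligodendrocyte, 0.13 for oligodendrocyte precursor, 0.87 for ependymal and choroid plexus, 0.16 for heat shock and 0.11 for histone modifying and DNA methylation genes. They were -0.25 for astrocyte, -0.43 for neuron, -0.18 for microglia, -0.41 for upper layer cortical neuron, -0.16 for cholesterol synthesis, -0.18 for GABA receptors and uptake and -0.15 for glycolysis. With an estimated correlation none passed. Without water homogenates 68 and 73 the oligodendrocyte (0.04), oligodendrocyte precursor (0.07), ependymal and choroid plexus (0.44) and histone (0.04) lists were not called. Without isolated libraries under 1000000 counts the neuron median was -0.00375, and the direction of camera turned.

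The first pattern is the higher level of mural markers in the isolated fraction of ethanol mice. A lower depth of the water libraries is argued against, since the difference was 0.313 ± 0.115 (SE) with every library thinned to the smallest total. Fewer cells of 1 other type, which would raise all remaining types alike, are argued against as the whole cause. With the neuron, oligodendrocyte, microglia and endothelial lists as covariates the difference was 0.392 ± 0.104, against 0.386 ± 0.128 without. That fit leaves out the astrocyte list, so it cannot decide on fewer astrocytes. Fewer astrocytes alone would leave mural minus microglial and mural minus neuron markers near 0. These differed by 0.550 ± 0.185 and 0.617 ± 0.293, and mural minus astrocyte markers by 0.599 ± 0.212. Against the other types the differences were under 2 SE from 0, at 0.311 ± 0.216 for oligodendrocyte, 0.317 ± 0.361 for oligodendrocyte precursor, 0.267 ± 0.164 for endothelial and 0.235 ± 0.185 for fibroblast markers, so these do not exclude a joint loss of several types. A higher mural level in the tissue before isolation also stays open, with a difference of 0.282 ± 0.252 between isolated fraction and homogenate of the same mouse. An effect of ethanol on pericytes or on their capture with astrocyte endfeet may be among the explanations and was not tested.

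The second pattern is the larger rise of microglial than astrocyte transcripts in the isolated fraction of water mice. Loss of neuronal RNA alone would raise both alike, and microglial minus astrocyte markers rose by 2.83 ± 0.232 more in the isolated fraction within a mouse. Loss of neuronal RNA alone is therefore argued against. The value was seen before this test was chosen, so it can count against that explanation and supports no other. No other technical explanation and no biological explanation was tested.

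The third pattern is the lower level of astrocyte markers, and of genes lower with them, in the isolated fraction of ethanol mice. Dilution by oligodendrocyte RNA would lower all the rest alike. It is argued against as the whole cause only by the fit with the oligodendrocyte list among 4 covariates, where the difference was -0.373 ± 0.0547. With that list alone the difference was -0.238 ± 0.142, and without covariates -0.213 ± 0.143. Both are under 2 SE from 0, so they cannot decide. The oligodendrocyte level itself differed by 0.0753 ± 0.121. Without libraries under 1000000 counts it differed by 0.169 ± 0.139, with 9 of 10 ethanol libraries above the water mean, and the astrocyte difference was -0.421 ± 0.0655 with the 4 covariates. With the main axis of the non-astrocyte markers as 1 covariate no gene was called. A lower share of astrocyte RNA, which by itself would not explain why mural and microglial markers moved apart, cannot be told apart from lower expression within astrocytes. Of the 159 genes outside the astrocyte list that were lower with 4 covariates, 0 remained with the astrocyte list as a further covariate, but their median SE also grew, from 0.0977 to 0.199. An effect of ethanol on astrocytes themselves therefore remains possible and untested.

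Libraries were regrouped at random to see whether chance can be excluded. For genes at an unadjusted p under 0.05, 23 of 100 splits gave as many as the 600 of the isolated fraction (highest other 1791), 64 of 100 as many as the 467 of the homogenate (2545) and 31 of 100 as many as the 834 of the difference between fractions (1323), so chance is not excluded for these. At an FDR under 0.05 the real count was 0 in each of the 3, which all 100 splits reach whatever the data, so this says nothing about chance. The highest counts of other splits were 25, 138 and 10. The 10412 genes between fractions of water mice were reached by 1 of 100 splits, the real one (highest other 3997). The 247 genes with 4 covariates were also reached by 1 of 100 (highest other 31). Chance is argued against for both, as far as 100 splits can show. For the 247 genes this covers 1 fit alone, since the main fit and the main axis of non-astrocyte markers as covariate gave 0. The 14 genes of the DESeq2 Wald test were reached in 6 of 50 splits (highest other 263), so chance is not excluded there. Single splits called many more genes than the real one, 138 in 1 split of the homogenate and 263 in 1 split of the isolated fraction with DESeq2. A structure of the samples other than treatment may be behind these and was not tested.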

How the results depend on the processing

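Thinned counts in the isolated fraction, covariates and the replicate block for lists, the mural list or 5 lists as covariates, and leaving out named libraries or Rn45s were chosen after seeing the data; the others were planned. In the isolated fraction, 0 genes higher under ethanol became 12 with the DESeq2 Wald test, 3 with limma voom, 1 without a filter, 5 in 1 fit of all 4 groups, 71 with 4 covariates, 2 with thinned counts and 1 at an FDR under 0.1, and 0 lower became 2, 2, 0, 2, 176, 0 and 0. Leaving out single libraries gave 0 to 14 higher (14 without ethanol 77, 10 without ethanol 75, 1 without water 82) and 0 to 1 lower (without ethanol 66). The counts were 0 and 0 under both scalings, with a mean of at least 50 counts, with the main axis of non-astrocyte markers, with the mural list or with 5 lists as covariates, without Rn45s, without libraries under 1000000 counts and without water 70 and 80. In homogenate all alternatives gave 0 and 0, each library left out included. For the difference between fractions DESeq2 gave 1 and 1 and voom 1 and 0. Leaving out single libraries gave 0 higher and 0 to 1 lower (without the isolated fraction of ethanol 66 or the homogenate of ethanol 76), and the other alternatives gave 0. Between fractions of water mice, thinned counts gave 3322 higher and 3283 lower, with 1924 at least 2-fold lower, since fewer genes were tested. Leaving out single libraries gave 4928 to 5080 higher, 5303 to 5474 lower, 2527 to 2640 at least 2-fold higher and 2926 to 3099 at least 2-fold lower. Lists called up and down fell to 0 and 0 with an estimated correlation and with fry in the isolated fraction, in homogenate and for the difference between fractions. In the isolated fraction 3 were up with thinned counts. In homogenate 1 was up and 2 down with 4 covariates, and 2 were down without water 68 and 73, which left 2 up for the difference between fractions. Between fractions of water mice 0 were up and 2 down with an estimated correlation, and 28 up and 10 down with fry. There 8 were down with the replicate block, which changed no other call. Marker levels passing in the isolated fraction went from 1 to 0 by median z-score and without libraries under 1000000 counts. Without libraries under 1000000 counts the median of the neuron list reversed in the isolated fraction (0.0829) and came close to 0 in the difference between fractions (-0.00375), where the direction of camera reversed. Medians reversed in homogenate for the oligodendrocyte (0.00970) and endothelial (-0.00068) lists with 4 covariates, of which each is one. Medians also crossed 0, without a change in the direction of camera, for the microglial list in the isolated fraction with 4 covariates (0.00201) and for the oligodendrocyte list in homogenate without water 68 and 73 (0.0158). Atp13a5 in the isolated fraction reversed to -0.0945 with 5 covariates. The other genes named by lowest p or largest change, with Pdgfrb, Kcnj8 and Abcc9, kept their direction in the alternatives run on them. Reversals were not counted for the remaining genes named only as list members. Where no cause is given, the cause was not tested. No library fell under the depth limit set relative to its group's median, so that alternative gave no value. At the depth of the isolated fraction 54% of simulated 1.5-fold changes were recovered with many genes changed at once, which limits smaller or rarer changes.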

Other observations

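Several gene groups not described above separated the fractions of water mice. Of 25 genes of Notch and Wnt signalling, 20 were higher and 2 lower in the isolated fraction (median log2 fold change 1.31), with the receptor genes Lrp5 at 2.47 ± 0.09, Notch3 at 2.62 ± 0.11 and Notch1 at 1.97 ± 0.10 (camera FDR 0.000264, adjusted p = 0.174 with an estimated correlation). Of 23 genes of the transforming growth factor and bone morphogenetic protein pathways, 16 were higher and 2 lower (median 0.65), led by Tgfb1 at 4.03 ± 0.15 and Tgfbr1 at 3.45 ± 0.14 (camera FDR 0.00560, adjusted p = 0.255 with an estimated correlation). Interferon response genes were higher in 15 of 16 cases (median 1.41), with Bst2 at 2.51 ± 0.17 (camera FDR 0.0119, adjusted p = 0.306 with an estimated correlation). Of 10 genes of ethanol and acetaldehyde metabolism, 8 were higher and 1 lower (median 0.78), with the catalase gene Cat at 1.49 ± 0.10 and the aldehyde dehydrogenase gene Aldh2 at 0.92 ± 0.08 (camera FDR 0.0448, adjusted p = 0.391 with an estimated correlation).

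Genes of the nuclear-encoded respiratory chain were lower in 54 of 75 cases and higher in 0 (median -0.56), with Cox8a at -1.71 ± 0.13 and Cox6a1 at -1.22 ± 0.12 (camera FDR 0.0258, adjusted p = 0.697 with an estimated correlation). Cytosolic ribosomal protein genes went both ways, 28 higher and 13 lower of 72 (median 0.26), and were not called (camera FDR 0.447). The circadian clock list was balanced, with 7 of 17 genes higher and 7 lower. Among genes outside the lists described for the isolated fraction of ethanol mice, the Notch receptor gene Notch3 stood at 0.58 ± 0.15 and the amino acid transporter gene Slc1a5 at 0.70 ± 0.17. Each was higher when adjusted over its list alone, whereas over all genes neither passed, with FDR 0.261 and 0.161. Both were chosen after their values were seen. In the striatal neuron and circadian clock lists 1 member each was lower when adjusted over the list alone. Aldh2, Notch1 and Notch3 overlap exons of genes on the opposite strand, so their counts are uncertain.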
